A study of Homo sapiens with 6 samples.

How the data were processed

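The study used HEK293 cells, an established human embryonic kidney line. Cells were transfected with a plasmid coding for the RBS1 part of Gemin5, the RBS2 part of Gemin5 or no Gemin5 sequence, in each case with a tandem affinity purification (TAP) tag. Per the labels' protocols, cells were irradiated 24 h after transfection with ultraviolet light of 254 nm at 150 mJ/cm2, which crosslinks proteins to the RNA they touch. Tagged complexes were then purified on IgG resin and calmodulin resin, and protein was removed with proteinase K. About 100 ng of RNA per library went into a stranded library preparation that left out the selection of polyadenylated RNA. The libraries were read as single reads of 50 bp. Each of the 3 groups had 2 independent biological replicates, 6 libraries in all.

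The deposited data are 3 lists of regions, each joint over the 2 libraries of its group. Each row gives a chromosome, start, end, strand, the sequence with 20 nt of flank on each side, a gene, a transcript, a gene biotype and an annotation class. It also gives a score, which the authors set per region and which is a whole number in every region. What the score counts, the read aligner, the region caller and any threshold are not given in the sources used here. The genome build is hg19, per the submitters' processing notes. Scores were used only to rank, match or filter regions. Read depths per library were not used here, so the depth behind a region is unknown beyond its score, and no value has a replicate error.

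Rows with the same coordinates and strand were joined into distinct regions, because a region annotated to several transcripts or classes stands in several rows. Region length was computed as end minus start plus 1, which equalled the length of the printed sequence in all 304 RBS1, 294 RBS2 and 17727 TAP regions. The annotation classes are those of the files: coding sequence, 5' UTR, 3' UTR, intron and NC. All NC rows belong to genes with a noncoding biotype. A region counts in each class it carries. Regions of different lists were called shared when they overlapped by at least 1 nt on the same strand. A gene was in a list when at least 1 region was annotated to it.

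Shares carry exact Clopper-Pearson intervals at the 95% level. A share of 0 is given with the limit that 3 counts of the total would make. Intervals and limits cover counting error only. Classes, gene lists and 4-mers were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 15 class tests, 60 list tests and 768 4-mer tests at a threshold of 0.05. Odds ratios had 0.5 added to each cell, and their 95% intervals were computed on the log scale. GC content (G and C bases as a percentage of the region) and region length were compared by the difference of medians with a two-sided permutation test of 100000 permutations, adjusted over 6 tests. The smallest p those permutations can give is 1e-05. Shared genes were tested with Fisher's exact test against the genes of any list. All of these tests treat regions or genes as units, so they compare lists and not replicated conditions. Regions and genes in both RBS lists count on each side, so comparisons of RBS1 with RBS2 treat overlapping lists as independent. Fits of signal per region or gene across libraries, which had been planned, could not be run on joint lists.

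The choices of groups, comparisons, 20 gene lists and most alternatives were fixed before the data were examined. Alternatives collapsed or merged rows, required longer regions or higher scores, changed the overlap rule or the background, counted genes instead of regions, and matched TAP regions on length or GC content. Those chosen after seeing the data required a score of 4 or more in every list, matched TAP regions on score, included flanks in 4-mers, used all protein-coding genes as background, or left out regions that share 12 nt with a high-score TAP region. Matching drew 5 TAP regions per RBS region, or 1 RBS2 region per RBS1 region. Regions with fewer matches were left out, so matched results describe the regions that could be matched. The score-matched GC differences under other observations instead kept every RBS region, with up to 5 TAP regions for each. The named genes follow a fixed rule. It takes the 10 genes with the highest score in each list, the 5 genes with most regions in each RBS list, up to 10 genes in both RBS lists, all members of the survival of motor neuron (SMN) complex, and up to 4 members of each other gene list. Genes with equal scores were ranked by longer region, then by order in the list. The rule also names up to 5 4-mers per direction and comparison.

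Gene lengths and current symbols came from a RefSeq table of assembly GRCh38.p14, which was used for names and lengths only. It matched 289 of 298 RBS1 genes, 281 of 287 RBS2 genes and 6689 of 7025 TAP genes. Regions were not annotated anew because no genome of the files' build was used here. The statistics were tested on simulated lists drawn from TAP regions at the sizes of each comparison, with 5000 regions standing for the TAP list. With 4 4-mers planted in 25% of regions, 80 of 80 planted 4-mers were recovered in each of the 3 comparisons. In 20 draws without a planted difference, at least 1 4-mer passed in 0 draws for RBS1 against TAP, 0 for RBS2 against TAP and 1 for RBS1 against RBS2. A class passed in 2, 0 and 0 of these draws, a gene list in 1, 0 and 0, and the GC test had a p under 0.05 in 2, 2 and 1. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.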

Results

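Gemin5 is the RNA-binding member of the SMN complex that recognises small nuclear RNAs, and it also acts on translation. Its C-terminal part holds a noncanonical RNA-binding site, of which RBS1 and RBS2 are separate pieces. The question was which cellular RNAs each piece contacts. RNA was crosslinked in HEK293 cells and purified with RBS1-TAP, RBS2-TAP or the TAP tag alone, with 2 libraries per group. The 3 lists analysed here hold 1 set of regions per group, so no value below has an error between replicates.

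The RBS1 list held 343 rows, which are 304 distinct regions in 298 genes. The RBS2 list held 323 rows, 294 regions and 287 genes. The list of the tag alone was far longer, with 20029 rows, 17727 regions and 7025 genes, 58.3 times the regions of RBS1 and 60.3 times those of RBS2. Scores, as the authors deposited them, were low in both RBS lists: the median was 3 in each, against 7 for TAP. A score of at most 3 was found for 75.3% of RBS1 regions, 80.3% of RBS2 regions and 16.3% of TAP regions. The highest scores were 14 in RBS1, 16 in RBS2 and 4773 in TAP. Protein-coding genes held 93.4% of RBS1 regions, 95.2% of RBS2 regions and 89.2% of TAP regions.

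The RBS1 region with the highest score lay in the coding sequence of GEMIN5, part of which the transfected plasmids also carry, so the regions are given by position and not by the transcript they came from. GEMIN5 (ENSG00000082516) had 4 RBS1 regions, the most of any gene in that list, all annotated as coding sequence on the minus strand of chromosome 5 (hg19). Position 154271122 to 154271206 (85 nt) had a score of 14, the highest of the RBS1 list, and the sequence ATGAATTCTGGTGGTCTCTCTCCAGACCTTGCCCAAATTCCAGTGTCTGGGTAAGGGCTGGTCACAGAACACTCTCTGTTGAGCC. Position 154270932 to 154270999 (68 nt) had a score of 7 and the sequence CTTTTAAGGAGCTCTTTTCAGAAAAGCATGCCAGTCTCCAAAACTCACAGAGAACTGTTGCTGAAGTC. The other regions, 154271028 to 154271055 (28 nt) and 154270870 to 154270923 (54 nt), each had a score of 3. Together they covered 235 nt, or 69.7%, of a stretch of 337 nt.

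**Figure D1:**
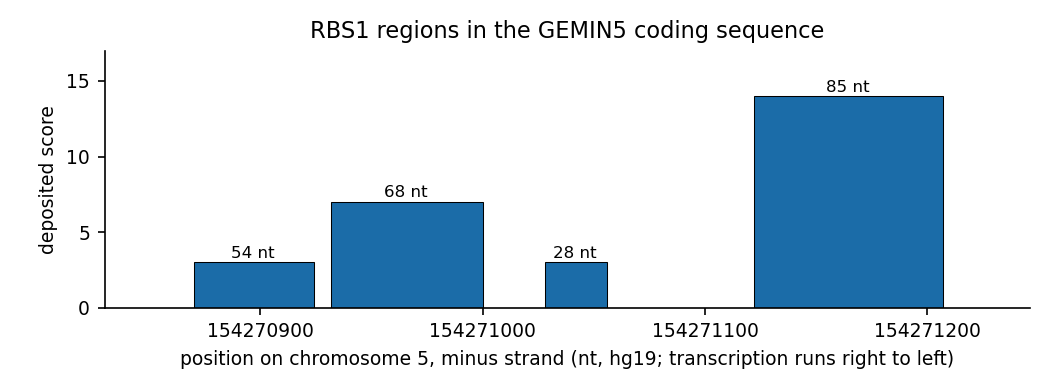
RBS1 regions in the GEMIN5 coding sequence. The x axis is the hg19 position on chromosome 5 in nt (minus strand), the y axis is the score the authors deposited, and each bar spans 1 region, with its length above it; the 85 nt region at the right has the highest score, 14.

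No GEMIN5 region was in the RBS2 list, where 0 of 294 regions allows a share of up to 1.02%. The TAP list had 2 GEMIN5 regions elsewhere, a 20 nt region in the coding sequence (154267843 to 154267862, score 40) and a 25 nt region in an intron (154303214 to 154303238, score 54). The nearest of these was 3007 nt from the RBS1 stretch. Counted over genes, the SMN complex, with GEMIN5 its only member in either list, did not pass in RBS1 against TAP (Fisher's exact test, p = 0.0797). The 4 regions are pieces of 1 stretch. Tests over regions, such as those of classes, of 4-mers and of gene lists counted over regions, still count them as 4 separate regions.

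Against the tag alone, RBS1 regions lay more often in coding sequence and 5' UTRs. Coding sequence held 42 of 304 RBS1 regions, 13.8% (95% interval 10.1 to 18.2), against 7.15% of TAP regions (odds ratio 2.10, Fisher's exact test, adjusted p = 0.00075). The 5' UTR held 6.58% (4.06 to 9.98) against 3.51% (odds ratio 1.98, Fisher's exact test, adjusted p = 0.0378). Introns held most regions of either list, 78.3% of RBS1 and 83.6% of TAP (odds ratio 0.706, Fisher's exact test, adjusted p = 0.0574). The intron difference passed at or above each list's median score (0.646, Fisher's exact test, adjusted p = 0.0169), with regions overlapping another list left out (0.672, adjusted p = 0.0393) and against TAP regions matched on score (0.582, adjusted p = 0.00527). The 3' UTR (3.95% against 5.94%, Fisher's exact test, adjusted p = 0.329) and NC (2.30% against 4.95%, adjusted p = 0.0781) did not pass, though NC did without regions that share 12 nt with a high-score TAP region (odds ratio 0.358, adjusted p = 0.0224). Among regions with a score of 4 or more, coding sequence had an odds ratio of 1.01 (95% interval 0.424 to 2.41, Fisher's exact test, adjusted p = 1.00) and the 5' UTR 3.33 (1.62 to 6.82, adjusted p = 0.0928), over 75 RBS1 regions. At or above each list's median score the 5' UTR did not pass either (odds ratio 1.86, Fisher's exact test, adjusted p = 0.0777). When each gene was counted once per class, the odds ratios were 0.867 for coding sequence and 0.852 for the 5' UTR, on the other side of 1 (Fisher's exact test, adjusted p = 0.682 for each). The 3' UTR (0.495, Fisher's exact test, adjusted p = 0.0416) and NC (0.281, adjusted p = 0.000236) passed instead. A gene with several regions has more chances to carry a class. At least 2 regions were found in 2857 of 7025 TAP genes and in 11 of 298 RBS1 genes. The count over genes therefore does not by itself show a depletion of these classes in RBS1.

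Besides GEMIN5, the RBS1 regions with the highest scores were in genes of varied function. OVOL2, a zinc finger transcription factor, had an intronic region on chromosome 20 (18037945 to 18037965, score 10). PCBP1, a poly(C)-binding protein, had one in its 5' UTR on chromosome 2 (70314687 to 70314711, score 6). TRAPPC10, a subunit of a vesicle tethering complex, had an intronic region of score 6. The pseudogene RP11-475J5.5 had a score of 7, and AC114546.1 a 5' UTR region of score 6. M6PR, a mannose 6-phosphate receptor, carried a 59 nt region in its 3' UTR with a score of 5. Intronic regions of C6orf89 and VSTM2B also had a score of 5. A score of 5 or more was found for 27 RBS1 regions, so the named ones with a score of 5 were chosen among ties by length. After GEMIN5, the genes with most RBS1 regions were GOLGA8A and the kinase gene GSK3B with 3 each, followed by 8 genes with 2 each, among them ATP11A and GRHL3.

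RBS2 regions differed from those of the tag alone in the NC class, which held 1.36% of RBS2 regions (95% interval 0.372 to 3.45) and 4.95% of TAP regions (odds ratio 0.297, Fisher's exact test, adjusted p = 0.0175). Among regions with a score of 4 or more this was an odds ratio of 1.49, on the other side of 1 (Fisher's exact test, adjusted p = 0.934). Against TAP regions matched on score it did not pass (0.387, Fisher's exact test, adjusted p = 0.09995), and the 5' UTR passed instead (2.33, adjusted p = 0.0456). Coding sequence held 10.2% of RBS2 regions (6.99 to 14.2), and the difference from TAP did not pass (odds ratio 1.498, Fisher's exact test, adjusted p = 0.112). The 5' UTR held 6.46% (odds ratio 1.94, Fisher's exact test, adjusted p = 0.0574), the 3' UTR 4.76% (adjusted p = 0.570) and introns 81.6% (adjusted p = 0.522).

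**Figure D2:**
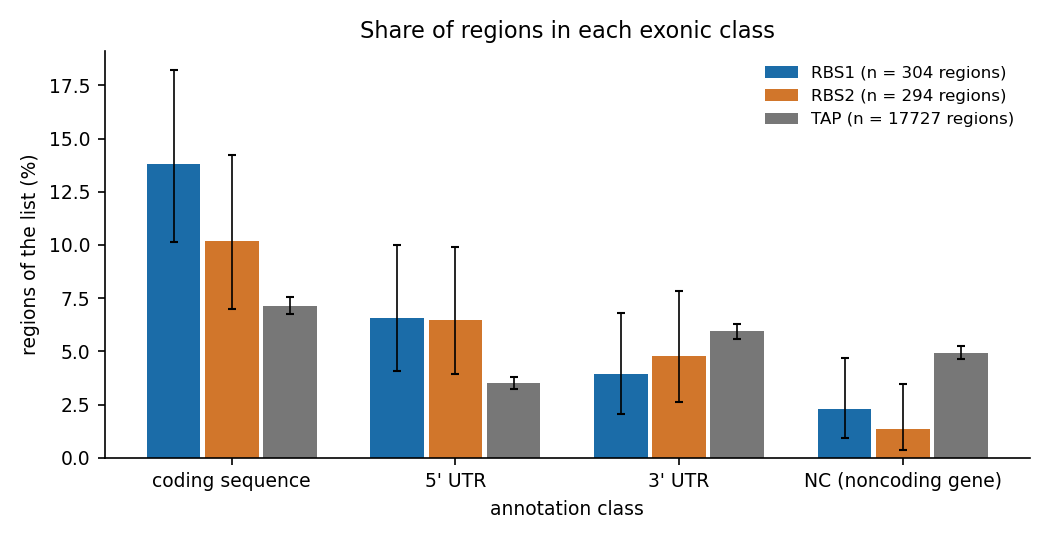
Share of the regions of each list (y axis, %) in coding sequence, 5' UTR, 3' UTR and the NC class of noncoding genes, for RBS1 (304 regions), RBS2 (294) and TAP (17727); error bars are exact 95% intervals that cover counting error only. Coding sequence holds 13.8% of RBS1, 10.2% of RBS2 and 7.15% of TAP regions.

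The highest RBS2 score, 16, belonged to the same OVOL2 intron position as in RBS1 (chromosome 20, 18037945 to 18037965). The pseudogene RP11-320M16.1 on chromosome 14 had a score of 14, FBXL19-AS1, an antisense RNA, a score of 7, and an intron of ZBTB20, a transcriptional repressor, a score of 6. Among the 10 named genes, scores of 5 were found for a 3' UTR region of AP4M1, an adaptor complex subunit, and for intronic regions of TMEM51, ITSN2, TERF2, PCBD2 and NMNAT2. A score of 5 or more was found for 14 RBS2 regions, so these were chosen among ties by length. TERF2 binds telomeres, and NMNAT2 makes NAD in neurons. The most regions per RBS2 gene were 2, in ITSN2, CORO2B, EFHC2, ABCA4 and MYO9A among others.

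The tag alone gave its highest scores at introns of UNC45B (chromosome 17, 33478112 to 33478374, score 4773), PID1 (3142), HFM1 (1476), RYR2 (1436), SLCO5A1 (1386), DLG2 (1217), INTS4 (1200) and PHKB (809). ARSI (5' UTR, 1301) and the pseudogene CTD-2328D6.1 (1200) completed the 10 highest. In the TAP list 750 regions had a score of 100 or more, and in the RBS lists 0. None of these 10 regions overlapped an RBS region on the same strand, which held for every TAP region and may stem from a removal before deposit (below).

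No RBS1 region overlapped a TAP region on the same strand: 0 of 304, which allows a share of up to 0.987%. The same held for 0 of 294 RBS2 regions, which allows up to 1.02%. If regions overlapping TAP were taken out before deposit, a possibility taken up below, both counts were fixed at 0. The limits would then say nothing about binding. Close neighbours were common: 23 RBS1 regions and 15 RBS2 regions lay 1 to 50 nt from a TAP region on the same strand. Within 100 nt were 29 RBS1 regions (9.54%) and 19 RBS2 regions (6.46%), and the difference between the lists did not pass (Fisher's exact test, p = 0.178). Within 1000 nt were 21.7% of RBS1 and 15.3% of RBS2 regions (Fisher's exact test, p = 0.0462, not adjusted for the other distances). Of the RBS1 genes, 182 (61.1%) were also in the TAP list, and of the RBS2 genes 176 (61.3%). Against the genes of any list, a background that the TAP list nearly fills, these counts lay below the 289 and 279 expected (odds ratios 0.0216 and 0.0230). That outcome was largely built in, because each gene of this background outside the TAP list is in an RBS list. It therefore shows no avoidance of TAP genes. Against all protein-coding genes of the RefSeq table the odds ratios were 3.81 and 3.91, on the other side of 1.

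**Figure D3:**
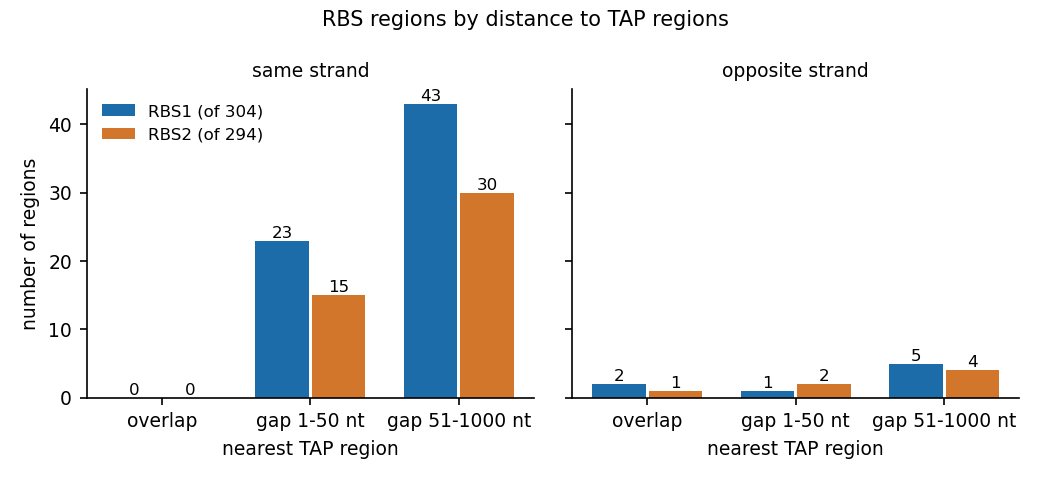
Number of RBS1 and RBS2 regions (y axis) that overlap a TAP region, lie 1 to 50 nt away or lie 51 to 1000 nt away (x axis), on the same strand (left) and on the opposite strand (right). On the same strand, 0 regions overlap while 23 RBS1 and 15 RBS2 regions lie within 50 nt.

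RBS1 and RBS2 shared 51 regions, 16.8% of RBS1 (95% interval 12.8 to 21.5) and 17.3% of RBS2 (13.2 to 22.2). Coordinates were identical in 24 of these pairs, and both ends lay within 3 nt in 46. The shared regions were short, with a median of 23 nt, and 41 of 51 were annotated as intron only. Examples with high scores were the OVOL2 intron (AATTGCCCGGCGGCGGGACCG, scores 10 and 16), FBXL19-AS1 (chromosome 16, 30933415 to 30933436, CGAATCCCCGCCCCGCCCCGGG, scores 3 and 7) and ZBTB20 (chromosome 3, starting at 114356845, scores 3 and 6). ITSN2, WWTR1, CEP128, SPOCK3, SV2C, ANP32A and SNTG1 were also shared, through introns. The regions of CEP128, SPOCK3 and SV2C had the same sequence in RBS1, and ITSN2 held most of it (below). These regions are therefore not independent, and which gene the RNA came from is ambiguous. The counts and intervals of shared regions take each as separate. EIF3H, a translation initiation factor subunit, shared an intronic region (score 3 in each). Chosen after its values were seen, a coding region of AGO2, the Argonaute protein of RNA interference, had identical ends in both lists (chromosome 8, 141561421 to 141561447, score 3 in each).

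At the level of genes, 57 were in both RBS lists, against 11.8 expected (odds ratio 6.93, Fisher's exact test, p = 1.41e-24). The odds ratio moved with the background, to 2.74 with only TAP genes of at least 2 regions and 22.6 with all protein-coding genes of the RefSeq table. A shared region accounted for 51 of the 57. The test took genes with the same shared sequence, such as CEP128, SPOCK3 and SV2C, as independent, so its p overstates the evidence. Without the shared regions, 6 genes were in both lists against 8.19 expected (odds ratio 0.775, Fisher's exact test, p = 0.586). No annotation class passed between RBS1 and RBS2; the adjusted p of Fisher's exact test was 0.348 for coding sequence (odds ratio 1.40), 0.522 for introns, 0.630 for NC, 0.740 for the 3' UTR and 1.00 for the 5' UTR, with 0 of 5 classes at an unadjusted p under 0.05.

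None of the 20 gene lists, which were set by symbol, passed in any comparison when counted over genes. By Fisher's exact test 0 of 60 tests passed, 0 had an unadjusted p under 0.05, and the smallest p was 0.0797, for the SMN complex in RBS1 against TAP. Raw counts below come from 298 RBS1, 287 RBS2 and 7025 TAP genes, and 0 genes allows a share of up to 1.01% in RBS1 and 1.05% in RBS2. Set by symbol, several lists also take in pseudogenes and related genes in TAP. Examples are EEF1A1P5 and EIF2AK2 (translation factors), HNRNPA1P7 (splicing regulators) and PSMC3IP (proteasome). Symbols of spliceosomal small nuclear RNAs, most of them pseudogenes such as RNU2-70P, had 0 genes in either RBS list and 18 in TAP (0.256%). Symbols of other short RNA polymerase III transcripts, mostly pseudogenes such as RN7SKP55, had 0 and 44 (0.626%), so the zeros show no depletion. The rRNA list had 0 and 3, the 5.8S pseudogenes RNA5-8SP2, RNA5-8SP3 and RNA5-8SP6, and small nucleolar RNAs had 0 and 6. RPL11, a ribosomal protein gene, had a coding region in RBS1 (score 3), against 38 cytosolic ribosomal protein genes in TAP. EIF2B3 and EIF3H were the translation factors in RBS1 (0.671% of genes) and EIF3H the only 1 in RBS2 (0.348%), against 37 in TAP (0.527%). RBS2 held MRPL44 (16 mitochondrial ribosomal protein genes in TAP), HIST1H2BE (32 histone genes), SF3B3 (20 splicing regulators) and RARS (7 aminoacyl-tRNA synthetases), and RBS1 held 0 of these lists. The chaperone list held DNAJC25 and its readthrough partner DNAJC25-GNG10 in RBS1, which share 1 region, 0 genes in RBS2 and 27 in TAP. Genes with a ZNF symbol, which leaves out other zinc finger genes such as OVOL2 and ZBTB20, numbered 6 in RBS1, among them ZNF587B, ZNF232, ZNF511 and ZNF28, 2 in RBS2 (ZNF202 and ZNF787) and 116 in TAP. Neither RBS list held a gene of the cell cycle list, mainly CDK, CDC and cyclin symbols (32 in TAP), a proteasome gene (13), a Sm or LSm protein gene (5), an actin or tubulin gene (3) or a snoRNA host gene (2). Mitochondrially encoded RNAs and the nuclear RNAs MALAT1 and NEAT1 were in 0 of the 3 lists. Counted over regions, the SMN complex passed in RBS1 against TAP (Fisher's exact test, adjusted p = 6.96e-05), through the 4 GEMIN5 pieces of 1 stretch.

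Both RBS lists were richer in G and C than the tag alone. The median GC content was 57.1% in RBS1, 59.1% in RBS2 and 50.0% in TAP, differences of 7.14 and 9.09 percentage points (permutation test, p = 1e-05 for each, the smallest these permutations can give). The difference between RBS1 and RBS2 did not pass (-1.95 points, permutation test, p = 0.402). The flanks differed too: their median GC content was 52.5% for RBS1 and 50.0% for RBS2, against 45.0% for TAP (permutation test, p = 1e-05, the smallest possible, and p = 0.00294). Median region length was 23 nt in RBS1, 22.5 nt in RBS2 and 25 nt in TAP. The difference from TAP did not pass for RBS1 (permutation test, adjusted p = 0.132) and passed for RBS2 (-2.5 nt, adjusted p = 0.0395). RBS1 regions were longer than RBS2 regions by 0.5 nt at the median (permutation test, adjusted p = 0.0485). Taking 1 region per gene, the median length was the same in RBS2 and TAP and in RBS1 and RBS2, and neither difference passed. For RBS2 against TAP the difference also did not pass among exonic regions (permutation test, adjusted p = 0.185) or at a score of 4 or more (adjusted p = 0.628), and at or above each list's median score it was 1 nt in the other direction (adjusted p = 0.375).

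The share of regions that hold a given 4-mer differed between the RBS lists and TAP. A longer region can hold more 4-mers. The upper quartile of length was 26 nt in RBS1, 24 nt in RBS2 and 40 nt in TAP. The shares below were not corrected for length except where regions were matched on it. Among all 4-mers, 80 differed between RBS1 and TAP after adjustment, 1 higher in RBS1 (CGGG, in 16.4% against 10.5% of regions) and 79 lower, led by TTTG (6.91% against 16.0%) and TGAT (4.61% against 12.4%). Between RBS2 and TAP 139 differed, 14 higher in RBS2, led by CCCG (20.1% against 10.0%), CGGC (18.7% against 10.1%) and GCGT (11.9% against 5.51%), and 125 lower, led by AAGA (2.04% against 13.0%). Against TAP regions matched on length and GC content, 0 4-mers passed Fisher's exact test with adjustment in either comparison, with 4 and 20 at an unadjusted p under 0.05. There 289 RBS1 regions met 1445 TAP regions and 279 RBS2 regions met 1395. The odds ratio of CGGG in RBS1 went from 1.70 (95% interval 1.25 to 2.30) to 1.25 (0.875 to 1.78), and those of GCGT and GTGA in RBS2 from 2.34 (1.64 to 3.35) to 1.98 (1.30 to 3.02) and from 0.175 (0.0804 to 0.382) to 0.248 (0.104 to 0.589). TAP sets of nearly the same size matched on score instead (1475 and 1375 regions) gave 33 passing 4-mers in RBS1, 11 higher and 22 lower, and 71 in RBS2, 17 higher and 54 lower (Fisher's exact test with adjustment). With flanks included, 10 were higher and 50 lower in RBS1. With 1 region per gene, CGGG did not pass (odds ratio 1.21, Fisher's exact test, adjusted p = 0.515) and 0 4-mers were higher in RBS1, while GCGT and CCCG stayed higher in RBS2. The balance of higher and lower 4-mers thus differed between settings. Between RBS1 and RBS2, 7 4-mers differed, all higher in RBS1, and 0 passed between regions matched on length and GC content, with 7 at an unadjusted p under 0.05.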

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

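The tests of chance placement, of carry-over, of gaps to TAP regions and of the GEMIN5 stretch were chosen after the results were seen, and the match length of 12 nt and the score limit of 100 were set after looking at the sequences.

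Direct tests between RBS1 and RBS2 passed for region length and for 7 4-mers. Both lists hold the 51 shared regions, so they are not the independent samples that these tests assume. The length and 4-mer tests were not run without the shared regions. The median RBS1 region was 0.5 nt longer (permutation test, adjusted p = 0.0485). The odds ratios of RBS1 against RBS2 were 4.40 for AAGA (8.88% against 2.04% of regions), 3.54 for GTGA, 2.57 for TGGT, 2.11 for GGTG, 2.44 for AGAA, 2.33 for TGAA and 2.33 for TGAG, by Fisher's exact test with adjusted p from 0.00246 to 0.0472. None of the 7 passed among regions with a score of 4 or more (75 and 58 regions), with flanks included or after matching on length and GC content (182 regions each). With 1 region per gene, AAGA, GTGA, GGTG and TGGT passed, while TGAA and TGAG did not. AGAA, which each GEMIN5 region of RBS1 holds, did not pass there either (odds ratio 2.01, Fisher's exact test, adjusted p = 0.216). The odds ratio of AAGA was 4.40 (95% interval 1.84 to 10.5) at first, 6.21 (1.60 to 24.2) after matching and 5.65 (0.286 to 112) at a score of 4 or more, where GGTG had 8.35 (2.13 to 32.7), TGGT 6.76 (1.71 to 26.7) and GTGA 3.59 (0.587 to 21.9). AGAA fell to 0.910 there, and the AAGA value rests on 3 of 75 against 0 of 58 regions. After matching, GGTG fell to 1.48 (0.676 to 3.23), TGGT to 1.90 (0.802 to 4.50) and GTGA to 2.37 (0.849 to 6.59), and with flanks AAGA fell to 1.13.

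No RBS region overlapped a TAP region on its own strand, although RBS and TAP regions were often neighbours. Pairs with a gap of 1 to 50 nt numbered 45 over both RBS lists, and given the widths of both windows 32.02 overlapping pairs would go with them, so chance with few regions does not account for 0. The binomial p of that split was 3.581e-11. On the opposite strand, RBS1 had 2 overlapping regions and 1 with such a gap, and RBS2 had 1 and 2. A candidate explanation is that regions overlapping the control on the same strand were taken out of the RBS lists before deposit; a true absence of binding at TAP sites, next to binding at their edges, was not tested separately. If such a step was applied, each comparison with TAP above describes what that step left.

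RBS1 and RBS2 shared 51 regions at nearly the same positions. Random placement within the 57 shared genes gave at most 4 shared regions in 10000 draws, so uniform placement along these genes does not account for them. Of the 57 genes, 51 were in this set through a shared region, and short regions placed uniformly rarely meet. Other forms of chance, such as uneven placement, were not tested. Carry-over between libraries would bring the strongest regions first. Of the 10 highest, 9 RBS1 regions were missing from RBS2 and 7 RBS2 regions from RBS1, and no difference from the other regions passed (Fisher's exact test, p = 1 and 0.386), so carry-over stays open. Misplaced fragments of abundant RNAs may be among the shared regions: 7 of the 51 held 12 nt of a TAP region of score 100 or more at another locus, above the upper limit of 3 in shuffled sequences and the 1 and 0 of their flanks (exact test, p = 0.0312 and 0.0156). The shuffles kept base composition but not simple repeats, so matches between repeats were not controlled for. No difference between shared and unshared RBS1 regions passed (Fisher's exact test, odds ratio 1.58, p = 0.444), and 16.5% of unshared RBS2 regions had a 12 nt match. Over whole regions 9 of the 51 held one, so such matches do not account for most of the shared regions. Whether misplaced fragments bring about the sharing of those 9 stays open. Fragments of RNAs outside the high-score TAP regions were not tested, and contact of both parts of Gemin5 with the same sites stays open too.

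The 4 RBS1 regions of GEMIN5 may come from binding of the cellular mRNA or from the transcript of the transfected RBS1 plasmid, which codes for part of Gemin5. They lie within 337 nt, and the list has no GEMIN5 region elsewhere. The RBS2 list held 0 GEMIN5 regions, although its plasmid also codes for part of Gemin5, so the part of the prediction for RBS2 was not met. That absence does not decide, because a removal of regions overlapping TAP could have taken out RBS2 regions at the TAP coding region of GEMIN5 (154267843 to 154267862). These origins cannot be told apart here, because the ends of the constructs are not given in the sources used here.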

How the results depend on the processing

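The alternatives with a score of 4 or more, matching on score, 12 nt matches, flanks, the RefSeq background and shared regions left out were chosen after the results were seen. In every alternative the GC content stayed higher in both RBS lists than in TAP. Other results moved as follows, and unless the construction shows it the cause was not tested.

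With regions of at least 30 nt only, 68 of 343 RBS1 rows, 27 of 323 RBS2 rows and 8122 of 20029 TAP rows stayed, in 54, 27 and 2156 genes. With a score of 4 or more, 81 RBS1 and 61 RBS2 rows stayed (75 and 58 distinct regions), in 73 and 58 genes, and the shared part fell to 6.67% of RBS1 and 8.62% of RBS2. Both lists were filtered, so a pair was lost when either of its regions scored under 4. The fall thus does not show that regions with higher scores are shared less. In this setting 0 classes passed in RBS1 against TAP and 0 in RBS2 against TAP, the NC odds ratio of RBS2 was 1.49, and 0, 0 and 0 4-mers passed for RBS1 against TAP, RBS2 against TAP and RBS1 against RBS2. AGAA turned to an odds ratio of 0.910 between RBS1 and RBS2, and median lengths differed by -2 nt (RBS2 against TAP) and 2 nt (RBS1 against RBS2), neither passing. At or above each list's median score 10258 TAP rows stayed (9112 distinct regions), and the length differences were 1 nt (RBS2 against TAP, the other direction) and 0 nt (RBS1 against RBS2).

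Counting neighbours within 100 nt as shared, 9.54% of RBS1 and 6.46% of RBS2 regions were shared with TAP. With shared regions left out, the odds ratio of genes in both RBS lists was 0.773 against the genes of the remaining lists (0.775 against the full background). With RefSeq protein-coding genes as background, those with TAP were 3.81 and 3.91, which follows from the larger background. With each gene counted once per class, the RBS1 odds ratios were 0.867 for coding sequence and 0.852 for the 5' UTR, and the 3' UTR (0.495) and NC (0.281) passed instead. That count gives genes with several regions more chances per class, and such genes were more frequent in TAP. With regions overlapping another list left out, 2 classes passed in RBS2 against TAP, the 5' UTR (2.25) beside NC. The intron difference of RBS1 from TAP passed there (0.672), at or above the median score (0.646) and with TAP matched on score (0.582). Gene lists counted over regions gave 1 passing list in RBS1 against TAP, through the GEMIN5 regions.

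With 1 region per gene, length differed by 0 nt in RBS2 against TAP and 0 nt in RBS1 against RBS2, and 30, 74 and 4 4-mers passed, with 0 higher in RBS1 and 2 higher in RBS2 than in TAP. Among exonic regions the length differences were -4 nt and 0 nt, neither passing. Without regions holding a 12 nt match, NC passed in RBS1 against TAP (0.358), 2 classes passed in RBS2 against TAP, length differed by -5 nt in RBS1 against TAP and now passed (permutation test, adjusted p = 0.000675), by 1 nt in RBS1 against RBS2 and no longer passed (adjusted p = 0.110), and 4 4-mers passed between RBS1 and RBS2. With TAP matched on score, length differed by -2 nt in RBS1 against TAP and now passed, the NC call of RBS2 ended (0.387), its 5' UTR passed (2.33), and 33 (11 higher) and 71 (17 higher) 4-mers passed. Of 5-mers 10, 43 and 0 passed, of 4-mers matched on length and GC content 0, 0 and 0 (GCGC in RBS2 against TAP turned to an odds ratio of 0.997), and with flanks 0 between RBS1 and RBS2.

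No paired analysis was possible because the files hold 1 joint list per group with no column per library. For the same reason leave-one-out fits, a replicate block and other fits of signal were not run, and own annotation was not run against a reference.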

Other observations

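All tests of this part were chosen after the data were seen, and only the predictions for shuffled sequences and for gene length were written before their own results.

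Regions with the highest TAP scores often shared sequence with each other. Of the 750 TAP regions with a score of 100 or more, 483 (64.4%, 95% interval 60.9 to 67.8) held in their first 20 nt a stretch of 12 nt found in another such region elsewhere in the genome. Their flanks did so in 8 cases upstream and 19 downstream. The share was 6.71% for TAP regions with a score of 5 or less. It was 10.2% (7.03 to 14.2) for RBS1 and 16.3% (12.3 to 21.1) for RBS2, both above low-score TAP regions (Fisher's exact test, odds ratio 1.60, p = 0.0267 and odds ratio 2.73, p = 3.5e-08). Shuffled RBS1 and RBS2 sequences, which kept base composition but not simple repeats, gave medians of 5 and 6 matches, against 31 and 48 observed. PCBP1, FBXL19-AS1, ANP32A, ROBO1 and SF3B3 were among the genes with such a region, and GEMIN5 was not. They were picked after their values were seen, PCBP1, FBXL19-AS1, ANP32A and SF3B3 being named by the fixed rule as well.

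A longer match of 18 nt at another locus was less frequent in TAP regions with a score of 100 or more (7.73%) than in those with 5 or less (16.7%; Fisher's exact test, odds ratio 0.421, p = 6.14e-12). A prediction of more such matches at high scores was withdrawn after this result. The 10 highest TAP regions were counted whole, unlike the shares above. CTD-2328D6.1 (463 nt) matched 20 other loci, SLCO5A1 (227 nt) 17, INTS4 (326 nt) 15 and HFM1 (370 nt) 11. PID1 (61 nt), ARSI (31 nt) and PHKB (36 nt) matched 0. Longer regions hold more stretches of 18 nt, so these counts cannot be set against those shares. Among all whole regions a match was found for 6.25% of RBS1, 5.44% of RBS2 and 23.2% of TAP. Length was not matched there, and its upper quartile was 26 nt in RBS1, 24 nt in RBS2 and 40 nt in TAP.

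Shared sequence also appeared within the RBS lists. The intronic shared regions of CEP128, SPOCK3 and SV2C, on chromosomes 14, 4 and 5, had the same 26 nt in RBS1, ACAAGCCGACCCTGACTTTCAGGAAG, each with a score of 5 in RBS1 and 3 in RBS2. ITSN2, on chromosome 2, held the last 23 nt of it.

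The GC content of regions exceeded that of their own flanks by a median of 5.13 percentage points in RBS1, 7.27 in RBS2 and 3.70 in TAP. The excess was higher than in TAP by 1.43 points in RBS1 (permutation test, p = 0.0447) and by 3.58 points in RBS2 (p = 9e-05). Against TAP regions matched on score the GC difference was 7.14 points for RBS1 and 9.09 for RBS2, and without regions holding the 12 nt matches 7.14 and 8.33 (permutation test, p = 1e-05 for each, the smallest possible). Predictions tied to these GC tests were withdrawn after a first look at their results, so they are given as values only.

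Intronic RBS regions lay in long genes. The median length of protein-coding genes with an intronic RBS1 region was 124.161 kb, against 125.756 kb for RBS2 and 130.348 kb for TAP, and against 24.0 kb for genes drawn without regard to length. One hypothesis was that such regions fall in proportion to gene length, as scattered fragments of unspliced transcripts could. Draws weighted by gene length gave a central 95% range of 137.684 to 213.688 kb for RBS1 and 137.636 to 215.09 kb for RBS2, above both observed medians. The TAP median also lay below its range of 166.077 to 177.638 kb, so placement by length over all protein-coding genes does not account for the values of any of the 3 lists, and the departure is no trait of RBS regions. Which genes these cells transcribe was not analysed here.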
